A study of Escherichia coli BL21(DE3) with 8 samples.

How the data were processed

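The files held 8 spotted oligonucleotide arrays with 2 colours and a table of processed values for the same arrays. Per the file headers, spots were quantified with Agilent Feature Extraction 9.5.1.1, which gave for each spot and channel a mean intensity and a median intensity of the local background, both not normalized. The authors' deposited log ratio is the log10 of red (Cy5) over green (Cy3), background-subtracted and dye-normalized by the same program per the file headers. The deposited table of processed values equalled that log10 ratio within 0.00248 for every spot, on the same scale and direction, with column medians between -0.00508 and 0, and it was not turned for the exchanged dyes. Per the series' design text, the authors combined ratio profiles weighted by their errors and asked for a 1.5-fold change with opposite ratios on dye-exchanged arrays. Strains, dyes and replicate numbers were taken from the labels. The labels call the replicates biological, and whether the same rne-ΔEBS-FLAG extracts served both sets is not stated in the sources used here.

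Mean intensities were corrected with the normexp method (offset 50) and normalized within each array by loess (span 0.3) in limma 3.58.1 under R 4.3.3, with 548 internal control spots and 96 Arabidopsis control spots at weight 0. Spots with an outlier flag were left out (36 to 188 gene spots per array), saturated spots were kept (at most 21 per array and channel), spots of a probe were averaged, and a gene was the mean of its probes. The 4286 probe names were matched to the E. coli K-12 MG1655 gene table (ASM584v2), used for names and neighbours alone: 2654 matched a current symbol, 512 a locus tag and 939 a synonym, and 181 kept the name in the files. The 47 names that end in -r, such as fhuB-r, are not explained in the files and were kept as features of their own. This left 4233 genes, of which 47 had more than 1 probe name, and 4192 were tested because 41 lacked an unflagged spot on some array. Probes had to be well above background in at least 1 channel on at least 4 of 8 arrays. That filter removed 0 probes, since the flag was set on 99.7% to 100% of spots per array and channel, Arabidopsis controls included, so it does not separate expressed from silent genes. The level of a strain was called at the control level where it did not exceed the 95th percentile of the Arabidopsis spots in the same channel of that array.

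Ratios were turned to rne-ΔEBS-FLAG over the comparator by the dyes in the labels, and the 2 arrays with exchanged dyes were averaged into 1 replicate, in which a constant dye bias cancels. limma (lmFit and eBayes) was fitted to the 4 replicate ratios with a coefficient per set and a shared spread (residual degrees of freedom 2, prior 5.16), and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison. Calls are genes under an adjusted p of 0.05. Of 39 gene lists of textbook regulons, 37 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Small RNAs such as SgrS were not analysed here. Named genes were the 12 largest rises and 12 largest falls per set among genes under an adjusted p of 0.05 with at least 1.5-fold change and the same sign on all 4 arrays, filled up with genes that met all but the test, plus rne, eno, pnp, rhlB, hfq, ptsG, the genes beside rne and up to 4 members of each shifted list. The design, the lists, this rule and all but 3 of the alternative settings were fixed before the data were examined.

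The procedure was tested on simulated arrays with the measured dye bias and spread of 4192 genes. With 200 changed genes per set, the share of 1.5-fold changes recovered was 97.7% in the rne-FLAG set and 97.9% in the wild type set, and 5.95% and 5.94% of calls were false. With 20 changed genes, 85.7% and 83.6% of 1.5-fold changes and 100% of 2-fold changes were recovered, and 13.2% and 12.7% of calls were false. A heat shock list shifted by 1.2-fold was called in 100% of simulations at the preset correlation and in 0% with an estimated correlation, in each set. Genes were drawn independently, so these simulations do not show how the preset correlation behaves where members of a list vary together.

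Alternatives covered the log ratio of Feature Extraction, no background correction, median centring, scaling between arrays, the deposited table, other filters, the brightest probe, saturated probes left out, each replicate left out, a fit of all 8 arrays with a dye effect, each set alone, the replicate number as a block and the study's own rule. Loess within the 32 print blocks, the filter on genes brighter than the Arabidopsis controls and a crossed block were added after seeing the data. So were the comparison of each strain's log2 level between the sets, with both dyes averaged, and 100 simulations of the overlap of unchanged sets that share the rne-ΔEBS-FLAG extracts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.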

Results

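RNase E, the endonuclease encoded by rne, is the scaffold of the RNA degradosome of Escherichia coli. The arrays compared transcript levels between a strain with the allele rne-ΔEBS-FLAG and 2 comparators, a strain with rne-FLAG and the wild type. The series title places the study in the recognition of RNA and protein by the degradosome and in riboregulation, and the comparisons ask which transcripts differ when the ΔEBS deletion is present. The labels do not spell out EBS. Total RNA came from broth cultures of E. coli BL21(DE3), a protein-expression strain of the B lineage. The labels also describe a stress treatment with glucose or α-methylglucoside, a sugar analogue that is taken up but not metabolised, without saying which arrays held treated cells. Each of 2 sets of arrays held 2 biological replicates, and each replicate was hybridised on 2 arrays with the dyes exchanged, which gave 4 arrays per set and 8 in all. The first set paired rne-ΔEBS-FLAG with rne-FLAG and the second paired it with the wild type. The label of the wild type names no FLAG tag. Ratios over the wild type can therefore hold an effect of the tag as well as of the deletion, and the second set cannot tell them apart. Every log2 ratio below is rne-ΔEBS-FLAG over the comparator, averaged over the exchanged dyes, with the limma standard error (SE) and n = 2 replicates. The labels call the replicates biological, and the p-values measure the spread between these samples. The number of arrays limits the precision, and the median SE over 4192 genes was 0.10 on the log2 scale in each set.

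The oligonucleotides were designed for E. coli K-12 and each was spotted in duplicate. Median gene signal above local background ran from 355 to 488 units in green (Cy3) and from 148 to 447 units in red (Cy5). Arabidopsis control oligonucleotides, which have no target in the bacterium, gave medians of 357 to 495 units in green, about the level of the median gene, and of 88.2 to 327 units in red, below the median gene on each of the 8 arrays. In all, 1430 genes, or 34.1% of those tested, were brighter than the 95th percentile of these controls, and ratios of the dimmer genes understate the change. As scanned, the arrays correlated with each other at r = 0.54 to 0.83 across genes whichever dye held rne-ΔEBS-FLAG, so a gene-specific dye bias was the main signal of a single array. Its standard deviation (SD) was 0.43 on the log2 scale, against 0.19 to 0.22 for replicate ratios after the exchanged dyes were averaged. Replicate ratios 1 and 2 correlated with this bias at -0.16 and 0.04 in the rne-FLAG set and at 0.22 and -0.05 in the wild type set, so its removal may be incomplete.

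The gene that carries the deletion gave ratios near 0 in both sets. The rne transcript measured 0.07 ± 0.15 (SE) over rne-FLAG and -0.11 ± 0.15 over the wild type, and neither passed the test. Its probe stood at the control level in both strains on 3 of 4 arrays of the first set and on 4 of 4 arrays of the second. The place of this probe relative to the deletion is not known, so the value does not check the labels. The other degradosome transcripts did not pass either. For pnp (polynucleotide phosphorylase) the ratios were 0.23 ± 0.16 and -0.45 ± 0.16, for rhlB (an RNA helicase) 0.02 ± 0.10 and -0.19 ± 0.10, and for eno (enolase) -0.31 ± 0.09 and -0.29 ± 0.09. The RNA chaperone transcript hfq gave -0.09 ± 0.11 and 0.08 ± 0.11. Of 27 measured genes of the degradosome and RNA decay, 0 rose and 0 fell in either set, whether adjusted over all genes or over the list alone, and the list test (camera) gave adjusted p = 0.173 and 0.473.

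Over rne-FLAG, 3 of 12 measured glp genes (glycerol use) and 3 of 11 measured nan genes (sialic acid use) were higher in rne-ΔEBS-FLAG. glpD, the aerobic glycerol 3-phosphate dehydrogenase, was 2.49-fold higher (log2 1.32 ± 0.09, adjusted p = 0.00376), glpF, the glycerol channel, was 2.08-fold higher (1.06 ± 0.10, adjusted p = 0.0122) and glpT, the glycerol 3-phosphate transporter, was 1.79-fold higher (0.84 ± 0.09, adjusted p = 0.0152). The neighbouring genes of sialic acid breakdown, nanQ (0.98 ± 0.10), nanK (0.93 ± 0.09) and nanE (0.79 ± 0.09), had adjusted p of 0.0152, 0.0122 and 0.0199. The 6-phosphogluconate dehydrogenase gene gnd (log2 2.07 ± 0.20, adjusted p = 0.0122) and the ferrichrome permease gene fhuB (1.58 ± 0.11, adjusted p = 0.00376) also passed. The probes of gnd and fhuB stood at the control level in rne-FLAG on all 4 arrays, and above it in rne-ΔEBS-FLAG on 3 of 4, so their ratios are limited by the background and are not ranked against the others. The probe of nanE stood at that level in rne-FLAG on 3 of 4 arrays, so its ratio is limited too.

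These were the 8 genes that passed in this set, all higher, and 0 passed as lower. At an unadjusted p under 0.05, limma gave 114 higher and 146 lower genes, and the fit of all 8 arrays with a dye effect called 15 higher and 17 lower. That fit counts arrays with exchanged dyes as observations (estimated correlation within a replicate -0.11). Its calls therefore do not rest on the spread between biological replicates alone. Without replicate 1 of this set 0 genes passed, without replicate 2 it was 3, and without either replicate of the other set it was 26 (15 higher and 11 lower). Centring each array on its median gave 12 higher and 3 lower, and loess within print blocks 14 higher and 10 lower.

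Several genes reached 1.5-fold with the same sign on all 4 arrays and did not pass the test. Upward 4 of these 9 were fhuB-r (a further feature for fhuB, 1.35 ± 0.18), ugd (UDP-glucose dehydrogenase, 1.19 ± 0.16), glpQ (glycerophosphodiesterase, 0.81 ± 0.11) and fhuA (the ferrichrome receptor, 0.72 ± 0.12), with adjusted p from 0.0526 to 0.0775. In rne-FLAG, ugd and fhuA stood at the control level on 4 of 4 arrays and fhuB-r on 3, so their ratios are limited by the background. Downward they were the chaperone and protease genes ibpA (-0.83 ± 0.14), groS (-0.78 ± 0.12), hslV (-0.75 ± 0.11) and dnaK (-0.74 ± 0.17), and the flagellar rod genes flgG (-0.61 ± 0.09) and flgF (-0.59 ± 0.16). The metabolic genes ribB (-0.79 ± 0.12), malP (-0.74 ± 0.12), upp (-0.63 ± 0.11), aphA (-0.63 ± 0.13) and gntT (-0.62 ± 0.09) also measured lower. The adjusted p of these lower genes ran from 0.0659 for groS, hslV and gntT to 0.450 for flgF.

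**Figure D1:**
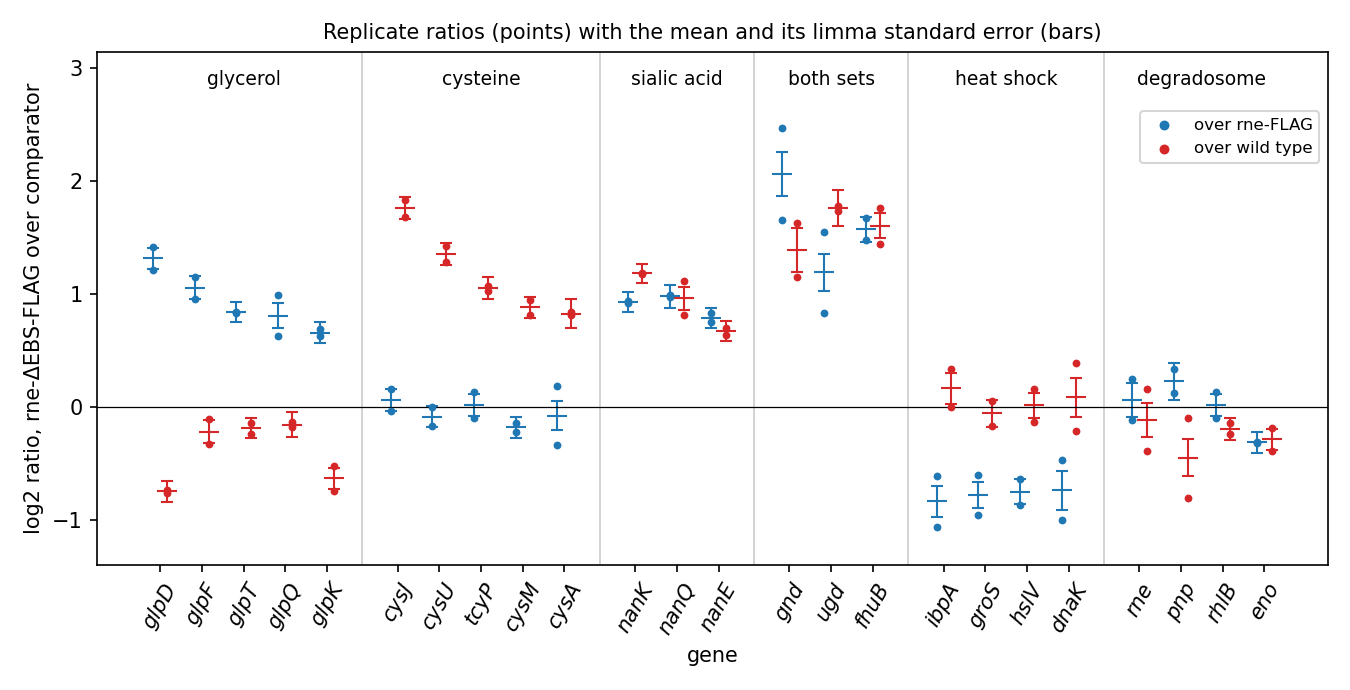
Log2 ratio of rne-ΔEBS-FLAG over its comparator (vertical axis) for genes of 6 groups (horizontal axis), over rne-FLAG in blue and over the wild type in red. Points are the 2 biological replicates, and bars give the mean and its limma standard error. Blue points lie above 0 and red points below 0 for the 5 glycerol genes, and for cysJ the red mean is 1.76 and the blue mean 0.06.

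Of the 37 lists tested, 8 shifted over rne-FLAG at the preset correlation between genes. The heat shock list moved downward (19 measured, median -0.31, camera adjusted p = 6.29e-10). None of its members fell at the threshold over all genes, and 9 fell when adjusted over the list alone. Its largest values were those of ibpA, groS, hslV and dnaK given above. The Fur regulon of iron acquisition moved upward (47 measured, median 0.13, adjusted p = 1.71e-08), with fhuB as the single member that rose over all genes and 10 that rose adjusted over the list alone. Its next members, fhuA, fhuF (0.68 ± 0.13) and fhuC (0.66 ± 0.11), did not pass. With an estimated correlation (0.04 for heat shock and -0.01 for Fur) both lists had an adjusted p = 0.490, and by fry it was 0.267 and 0.125. In simulations with genes drawn independently, the test with an estimated correlation called 0% of heat shock lists shifted by 1.2-fold.

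The other 6 shifted lists were weaker. In the list of carbon catabolism genes activated by CRP, 4 of 58 members rose and 0 fell over all genes, while 9 rose and 7 fell adjusted over the list alone (adjusted p = 0.0356). The 4 were glpD, glpF, glpT and nanE, and glpQ, glpK (0.66 ± 0.10) and the sialic acid transporter gene nanT (0.68 ± 0.09) came next without passing over all genes. All 7 that fell over the list alone were maltose genes, among them malM (-0.91 ± 0.14), malP and malQ (-0.70 ± 0.13), so members of this list lay on both sides of 0. Ribosomal protein genes (53 measured, median 0.14, adjusted p = 7.28e-05) and aromatic amino acid genes (14 measured, median 0.12, adjusted p = 0.00436) had 0 members that rose under either adjustment, with rplF at 0.40 ± 0.36, rpsM at 0.34 ± 0.12, trpA at 0.27 ± 0.14 and aroG at 0.18 ± 0.11. Downward shifts were measured for purine synthesis (15 measured, median -0.16, adjusted p = 7.28e-05; purD -0.56 ± 0.12), pyrimidine synthesis (15 measured, median -0.12, adjusted p = 8.73e-04; upp as above, pyrI -0.44 ± 0.12) and flagella and chemotaxis (49 measured, median -0.03, adjusted p = 0.00769). Adjusted over the list alone, 1 purine, 2 pyrimidine and 5 flagellar genes fell, and 0 did over all genes. With an estimated correlation the adjusted p was 0.490 for the CRP, aromatic, pyrimidine and flagellar lists and 0.760 for the ribosomal and purine lists. That correlation was 0.34 for the ribosomal and 0.34 for the purine list, far above the preset 0.01. By fry the adjusted p of the 6 lists ran from 0.0881 (CRP) to 0.620. Without replicate 1 of this set, the CRP, ribosomal, purine, pyrimidine and flagellar calls were lost (adjusted p from 0.0828 to 0.903), and without replicate 2 the CRP and aromatic calls were lost (0.167 and 0.370).

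Over the wild type, 3 of 22 measured genes of cysteine synthesis and sulphate assimilation and the cystine transporter gene tcyP were higher in rne-ΔEBS-FLAG. cysJ, the flavoprotein of sulphite reductase, was 3.39-fold higher (1.76 ± 0.10, adjusted p = 0.0013), and cysU, a sulphate permease subunit, was 2.56-fold higher (1.36 ± 0.10, adjusted p = 0.00219). tcyP (1.05 ± 0.10) and the cysteine synthase gene cysM (0.88 ± 0.09) also rose, with adjusted p of 0.00609 and 0.0115. The sialic acid genes nanK (1.18 ± 0.09), nanQ (0.97 ± 0.10) and nanE (0.67 ± 0.09) rose in this set too, as did fhuB (1.61 ± 0.11) and fhuB-r (1.59 ± 0.18). Further rises were ugd (1.76 ± 0.16, adjusted p = 0.00609), the galactose permease gene galP (1.08 ± 0.09, adjusted p = 0.00407) and rplY, the gene of ribosomal protein L25 (0.71 ± 0.09, adjusted p = 0.029). The glycerol gene glpD fell by 0.75 ± 0.09 (adjusted p = 0.029). For nanQ and glpD the sign was not the same on all 4 arrays, which places both outside the rule for named genes in this set. The probes of ugd and nanE stood at the control level in the wild type on all 4 arrays, those of nanK and nanQ on 3, and those of fhuB, fhuB-r and cysM on 2. The ratios of these genes are therefore limited by the background and not exact. Probes of glpD, glpF and glpT stood at that level in rne-ΔEBS-FLAG on 4 of 4 arrays and in the wild type on 2, 4 and 3. A ratio near 0 for glpF (-0.22 ± 0.10) or glpT (-0.19 ± 0.09) therefore says little. Of 19 settings 10 ended the call of rplY (log2 down to 0.47, adjusted p up to 0.180), and of 18 settings 10 ended that of nanE (0.26, adjusted p up to 0.463).

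These were the 13 genes that passed in this set, 12 higher and 1 lower. At an unadjusted p under 0.05 limma gave 192 higher and 141 lower genes. Without replicate 2 of this set 8 genes passed, all higher, and without replicate 1 it was 10 higher and 4 lower. The fit of all 8 arrays with a dye effect called 24 higher and 8 lower. With loess within print blocks 17 were higher and 5 lower, and without background correction 6 were higher and 0 lower. At 1.5-fold and the same sign on all 4 arrays, gnd measured 1.39 ± 0.20 (adjusted p = 0.0519) without passing. The genes rdgC (-0.65 ± 0.09), rsmG (-0.63 ± 0.10) and upp (-0.59 ± 0.11) measured lower, with adjusted p of 0.0573, 0.0953 and 0.143.

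The genes beside rne were measured in both sets, and 0 of 10 passed over all genes. Adjusted over the list alone, yceD passed over the wild type. Over the wild type, yceD gave 0.85 ± 0.15 (adjusted p = 0.122) and its neighbour rpmF, the gene of ribosomal protein L32, gave 0.63 ± 0.19 (adjusted p = 0.479), while over rne-FLAG they gave 0.27 ± 0.15 and 0.19 ± 0.19. For plsX the ratios were 0.09 ± 0.09 and 0.27 ± 0.09, for fabH -0.13 ± 0.10 and -0.06 ± 0.10, for rluC -0.17 ± 0.17 and 0.03 ± 0.17, for yceF -0.01 ± 0.12 and -0.01 ± 0.12, and for yceQ -0.04 ± 0.14 and 0.07 ± 0.14. The flagellar genes flgJ, flgK and flgL lay between -0.26 and -0.14 over rne-FLAG and between -0.19 and 0.04 over the wild type. The glucose transporter transcript ptsG, a target of the phosphosugar stress response, gave -0.03 ± 0.09 and -0.07 ± 0.09. Of 12 measured genes of that response, 0 passed over all genes and yigL, a sugar phosphatase gene, fell adjusted over the list alone in each set (-0.52 ± 0.09 and -0.40 ± 0.09), with list tests at adjusted p = 0.972 and 0.150.

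Over the wild type, 4 lists shifted at the preset correlation. In the cysteine and sulphate assimilation list (22 measured, median 0.18, adjusted p = 1.26e-07) 3 members rose over all genes, cysJ, cysU and cysM, while 9 rose and 1 fell adjusted over the list alone. The next member was cysA at 0.83 ± 0.13, which did not pass. In all 18 members lay above 0 and 4 below, and the size varied widely, with cysP at 0.45, cysI at 0.36, cysW at 0.21 and cysH at 0.02. Ribosomal protein genes (53 measured, median 0.13, adjusted p = 2.55e-06) had 1 member that rose over all genes, rplY, and 4 that rose adjusted over the list alone. Others of the list that did not pass over all genes were rpmE (0.83 ± 0.17), rpmF and rpmI (0.56 ± 0.11). Purine synthesis genes (15 measured, median -0.13, adjusted p = 5.99e-04) and pyrimidine synthesis genes (15 measured, median -0.15, adjusted p = 0.0167) shifted downward with 0 members that fell over all genes. Adjusted over the list alone, 0 and 1 fell. Values of single members were -0.52 ± 0.22 for purB, -0.50 ± 0.15 for purM and -0.26 ± 0.09 for pyrD. With an estimated correlation all 4 lists had an adjusted p = 0.789. By fry the adjusted p was 0.230 for the cysteine list and 0.565 to 0.672 for the others. Without replicate 1 of this set the ribosomal list pointed downward and its call was lost, so its upward shift rests on replicate 1. The purine and pyrimidine calls were lost without replicate 2.

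The difference between the sets, tested directly, passed for glpD, where the ratio over the wild type less that over rne-FLAG was -2.06 ± 0.13 on the log2 scale (adjusted p = 0.00368), and the glycerol genes glpK (-1.29 ± 0.14), glpF (-1.28 ± 0.14) and glpT (-1.03 ± 0.12) differed in the same direction. In the wild type set glpD, glpF and glpT stood at the control level in rne-ΔEBS-FLAG on 4 of 4 arrays and glpK on 2, and in the wild type on 2, 4, 3 and 2, so these 4 differences and the level gaps below are limited by the background and are not exact. The log2 level of glpD in rne-ΔEBS-FLAG itself was 12.38 in the rne-FLAG set and 7.42 in the wild type set, a gap of 4.96. For glpK, glpF and glpT the gaps were 4.54, 3.76 and 3.51, against a median of 0.63 over all genes, and the comparators had gaps of 2.90 (glpD), 3.24 (glpK), 2.48 (glpF) and 2.48 (glpT). Gaps in the same direction were measured for nanK (2.19 in rne-ΔEBS-FLAG and 2.45 in the comparators) and nanQ (2.52 and 2.51), past the 99th percentile of all genes (1.87 and 1.86), so the levels of these genes differed between the sets while their ratios did not pass as different. The wild type stood at the control level on 3 of 4 arrays for both, so these gaps are limited by the background too. The genes cysJ (1.70 ± 0.14), cysU (1.44 ± 0.14) and cysM (1.06 ± 0.13) differed the other way. These 7 genes passed, with adjusted p from 0.00368 to 0.0396, and glpK, the glycerol kinase gene, is named here although it did not pass in either set (0.66 ± 0.10 and -0.63 ± 0.10). For tcyP the difference was 1.04 ± 0.14 (adjusted p = 0.0597) and for galP 0.75 ± 0.13 (adjusted p = 0.190). For fhuB (0.03 ± 0.16), nanK (0.25 ± 0.12), nanQ (-0.02 ± 0.14), gnd (-0.68 ± 0.28) and ugd (0.57 ± 0.23) no difference passed. For gnd and ugd the comparators stood at the control level on 4 of 4 arrays in each set, so these values are limited by the background too. Without replicate 1 or replicate 2 of the rne-FLAG set, 1 and 0 differences passed, and without replicate 2 of the wild type set 3 did. Median centring left 4, the replicate number as a block 2, the fit of all 8 arrays with a dye effect gave 10 above and 4 below, and loess within print blocks 5 above and 4 below, in place of 3 and 4. All arrays of a set were scanned on a day of their own, so set and scan day cannot be told apart.

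**Figure D2:**
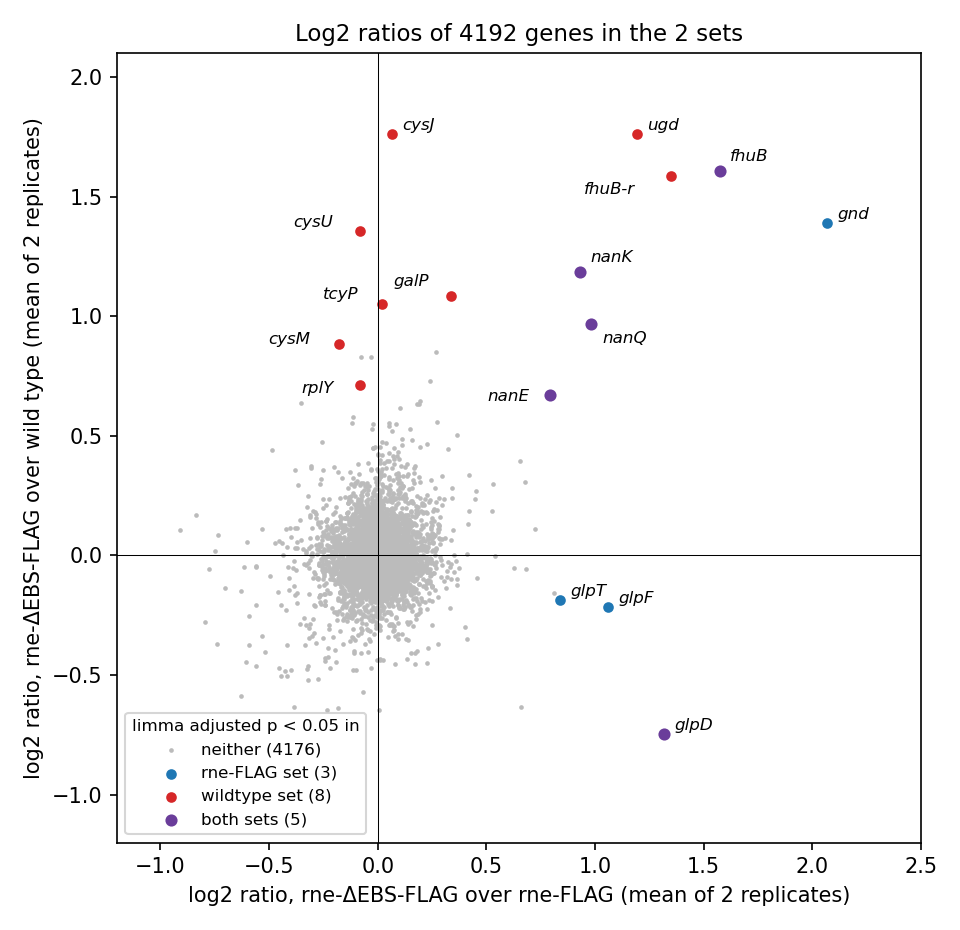
Log2 ratio over rne-FLAG (horizontal axis) against log2 ratio over the wild type (vertical axis) for 4192 genes, each the mean of 2 replicates. Colours mark the genes past an adjusted p of 0.05 in the rne-FLAG set alone (3), the wild type set alone (8) or both (5). The 5 genes in both are fhuB, nanK, nanQ and nanE at the upper right and glpD at the lower right.

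Across all 4192 genes the ratios of both sets correlated at r = 0.21 (Spearman rho = 0.06), and genes are not independent replicates. Both sets hold rne-ΔEBS-FLAG RNA, and unchanged sets that share those extracts gave a mean r of 0.50 in 100 simulations. The covariance was 0.00488 against 0.00596 in the simulations, and the labels do not say whether extracts were shared. The measured r lay far below the simulated one, and levels such as that of glpD in rne-ΔEBS-FLAG differed between the sets (gap 4.96). The data thus depart from the simulated setting, and whether the sets covary beyond a shared arm cannot be decided. Replicates of a set correlated at 0.20 in each set. The 4 genes fhuB, nanK, nanQ and nanE passed as higher in both sets and glpD passed with opposite signs. The first 4 stood at the control level in the wild type on 2, 3, 3 and 4 of 4 arrays, and in rne-FLAG on 4, 0, 1 and 3. In the wild type set, where glpD in rne-ΔEBS-FLAG stood at the control level on 4 of 4 arrays, its call was lost without background correction, without replicate 2 of that set and with the replicate number as a block (0 lower calls in each). Unchanged sets with shared extracts had 0.02 genes that passed in both sets on average and at most 1 in 100 simulations. The call of nanE was lost in 10 of 18 settings over the wild type and in 6 of 18 over rne-FLAG. At an unadjusted p under 0.05, 19 genes were higher in both sets and 28 lower in both. Independent sets would give 5.22 and 4.91, and simulated shared extracts gave means of 24.2 and 23.7, with at most 36 each. These overlaps lie above those of independent sets and below the highest simulated ones. Taken alone, they do not decide whether the sets agree beyond a shared arm. Opposite signs were measured for 12 genes, against at most 3 in the simulations of shared extracts, so the data depart from that setting. In rne-ΔEBS-FLAG, glpD, glpK, glpF and glpT had level gaps between the sets of 3.51 to 4.96 (99th percentile of all genes 1.87). For these genes the gaps argue against the same extracts in both sets. A slide or scan batch that shifts single probes was not tested.

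The list of genes missing or disrupted in BL21(DE3), which stands for a mixture with another strain, did not shift in either set. Its 17 measured members had medians of 0.05 and 0.01, with list tests at adjusted p = 0.626 and 0.952, and 0 members passed.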

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

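The tests of dye bias for the cysteine genes were written before their result was seen. All other tests of explanations in this part were chosen after it.

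The glycerol genes glpD (difference -2.06), glpK (-1.29), glpF (-1.28) and glpT (-1.03) stood out because the set effects differed by a test of the difference itself, as did cysJ (1.70), cysU (1.44) and cysM (1.06). On single arrays, a Dixon test of the 4 arrays of a set singled out fhuF over rne-FLAG, where replicate 2 with rne-ΔEBS-FLAG in Cy5 gave 1.59 and the other arrays 0.29 to 0.47, and flgF over rne-FLAG, where replicate 1 with rne-ΔEBS-FLAG in Cy3 gave -0.79 and the others -0.53 to -0.52. These were 2 of 99 gene and set combinations. Chance would give about 4.95 for 4 exchangeable arrays. Arrays with exchanged dyes and a gene-specific dye bias are not exchangeable, so the chance rate here is not known.

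For the 4 glycerol genes, the difference of the sets was taken within a single dye orientation, where a constant dye bias cancels by design. Its median over the genes was -1.16 with rne-ΔEBS-FLAG in Cy5 and -1.77 in Cy3. Over all 12 measured glp genes it was -0.39 and -0.40. The 4 genes were picked for their difference over both orientations, so these values are no separate test of a dye bias. The difference of glpQ was -0.97 and did not pass, and those of glpA, glpB, glpC, glpE, glpG, glpR and glpX lay between -0.26 and -0.02. A shift of all carbon catabolism genes under CRP is argued against by the 50 members of that list that are not glp genes, whose median difference was 0.0295 (quartiles -0.09 and 0.19). A scan day or slide batch that differs between the sets cannot be told apart from the comparator, since 0 scan days held arrays of both sets. A difference between rne-FLAG and wild type cells alone would leave rne-ΔEBS-FLAG alike in both sets, but its log2 levels of glpD, glpK, glpF and glpT were higher in the rne-FLAG set by 4.96, 4.54, 3.76 and 3.51, past the 99th percentile of all genes (1.87). Why these measured levels differ was not tested, and cells and scan day cannot be told apart here.

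For the cysteine genes cysJ, cysU, cysM and tcyP, the difference of the sets within a dye orientation had a median of 1.44 in Cy5 and 1.34 in Cy3. A constant dye bias cancels there by design. The genes were picked for their ratios over the wild type, which enter this difference, so it is no separate test of such a bias. A shift of all amino acid biosynthesis genes is argued against by the 65 members of the other amino acid lists, whose median ratio over the wild type was 0.0192 (quartiles -0.04 and 0.11). A scan day or slide batch that differs between the sets could not be separated here either, with 0 shared scan days, and a biological difference of the wild type from both tagged strains stays open, although cysJ, cysU and tcyP levels in rne-ΔEBS-FLAG also differed between the sets (gaps of -0.28, -1.14 and -0.39, with -0.16 as the 1st percentile of all genes), while cysM had 0.54, near the median of 0.63. A lower level in the wild type would place the comparator gap above its median over all genes, 0.65 (99th percentile 1.86). The gaps of cysJ (1.41) and cysM (1.60) lay above that median, and those of cysU (0.30) and tcyP (0.64) did not.

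The genes gnd, ugd and fhuB measured higher over both comparators, and gnd and ugd are neighbours in the K-12 gene table. A constant dye bias cancels in the mean over exchanged dyes by design, and the lowest of the 6 set means of these genes was 1.19 ± 0.16 (ugd over rne-FLAG). The genes were picked for these same means, so this value is no separate test of such a bias. A higher dose or expression of the whole gnd and ugd region is argued against by its neighbours: of 10, the 3 brighter than the controls (hisA, hisF and wzzB, all on the ugd side) had a median of 0.0859 and a highest value of 0.24, while the dim wbb genes on the gnd side leave that side open. A probe sequence difference between the strains, with K-12 probes that bind comparator RNA poorly, is a candidate explanation: the comparator log2 level less the Arabidopsis percentile had a median of -1.31, and was at or below 0 in 22 of 24 combinations. A rise of these transcripts from a low level would give the same values and stays open. Over the wild type the other fhu genes did not pass, with fhuA at 0.11, fhuC at 0.39, fhuD at 0.11, fhuE at -0.06 and fhuF at -0.06. Over rne-FLAG they gave 0.72, 0.66, 0.28, 0.03 and 0.68, again without passing.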

How the results depend on the processing

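Loess within print blocks, the filter on bright genes and the crossed block were chosen after the data were seen. Over rne-FLAG (8 calls), 15 genes passed with median centring, 24 with print-block loess, 32 with all 8 arrays and a dye effect and 26 with this set alone, each time with all 8 main calls among them, and 23 met the study's rule, again with all 8. Over the wild type (13 calls), 6 passed without background correction, all among the 13, 22 with print-block loess (12 shared), 32 with 8 arrays and a dye effect (13 shared), and 21 met the study's rule (11 shared). For the difference between the sets (7 calls), 4 passed with median centring and 14 with 8 arrays and a dye effect. Leaving out each replicate in turn gave 0 to 26, 8 to 14 and 0 to 6 calls. When a set keeps 1 replicate, that replicate is assumed to vary like the other set. The fit of all 8 arrays counts arrays with exchanged dyes as observations, so its counts do not measure the spread between biological replicates alone. Of 12 list calls, 0 held with an estimated correlation, fry gave 1 call, for another list, and leaving out each replicate gave 7 to 14 calls. Of the 19 named results that passed, 12 passed without background correction and 9 to 17 without a replicate. The cause was not tested in these cases, except that a left-out replicate leaves fewer values. Apart from the blocks below, all other alternatives stayed within 1.5 times the main count, and the correlation of the sets stayed between 0.16 and 0.31. Single replicates of the same number, not counted among these, correlated at 0.16 (replicate 1) and -0.13 (replicate 2). Of 1859 recomputed values of single named genes, 1635 kept their direction and side of the threshold, 48 lost and 137 gained a call, and 39 that passed neither time changed sign; 0 called values reversed.

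The replicate number as a block left 6, 11 and 2 calls. The numbers do not pair the sets: deviations of same-numbered replicates correlated at -0.30, so a crossed pairing, which the labels do not give, may exist. The crossed block gave 61 (27 higher, 34 lower), 99 and 36 calls. The block was chosen after the data were seen and fitted to these same deviations, so larger counts do not test that pairing. If the pairing holds, the counts of 8 and 13 and the 0 lower genes over rne-FLAG could be too low. The level gaps of the glycerol genes given above argue against shared extracts. A slide or scan block was not run, since each scan day held a single set, and the study's rule has no form for the difference of the sets. Signal over background limits the rest: 1430 of 4192 genes were brighter than control oligonucleotides, and changes of the others are understated.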

Other observations

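The tests of list differences and of single members in this part were chosen after the results were seen.

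All 37 lists were also tested for a difference between the sets with camera, and 5 differed. The cysteine list was higher over the wild type (22 measured, median difference 0.20, adjusted p = 6.98e-08), with cysJ, cysU and cysM past the threshold over all genes. Heat shock genes differed upward (19 measured, median difference 0.46, adjusted p = 6.98e-08), with 8 members past the threshold adjusted over the list alone and 0 over all genes. Over the wild type ibpA, groS, hslV and dnaK gave ratios of 0.17, -0.06, 0.02 and 0.09. The Fur regulon differed downward (median -0.13, adjusted p = 1.37e-04) and the targets of the iron-responsive small RNA RyhB upward (18 measured, median 0.14, adjusted p = 0.0189). The 10 genes beside rne had a difference above 0 in 10 of 10 cases (median 0.18, adjusted p = 0.0189). Of the 8 lists that shifted over rne-FLAG, the ribosomal, flagellar, CRP, aromatic, purine and pyrimidine lists did not pass this test (adjusted p from 0.0963 to 0.926). In the CRP list 4 members still differed over all genes, glpD, glpF, glpK and glpT, and 11 of 14 aromatic genes lay below 0 (median -0.14). With an estimated correlation the adjusted p of the 5 differences lay between 0.673 and 0.908, so none of them held in that form of the test.

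Outside the named genes, and picked after their values were seen, the maltose genes malM (-0.91), malQ (-0.70), lamB (-0.60) and malE (-0.56) measured lower over rne-FLAG beside malP, with adjusted p from 0.0732 to 0.495 over all genes and signs that differed between arrays. Over the wild type malM gave 0.10 and lamB 0.06. The sialic acid transporter gene nanT gave 0.68 over rne-FLAG (adjusted p = 0.0587) and 0.31 over the wild type, and nanA, the lyase gene of the same operon, gave 0.34 and 0.24.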
